A study of Mus musculus with 22 samples.

How the data were processed

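RNA was sequenced from KSIC_c806, a mouse pancreatic cancer cell line that carries an activated Kras allele and lost Cdkn2a and Smad4 through Pdx1-Cre recombination. The 16 RNA-seq libraries fell into 2 experiments of 8 libraries, each with 4 groups of 2 replicates. In the first, serum-starved cells with an empty vector (Vector) or with Smad4 restored (Smad4RE) received 100 pM TGFb1 for 90 min or 2.5 µM of a type I TGFb receptor inhibitor for 2 h. In the second, Smad4-restored cells with a doxycycline-inducible shRNA against Sox4 received 100 pM TGFb1 or 2.5 µM of the inhibitor for 24 h, without or with 1 µg/ml doxycycline, and all were given the Akt inhibitor MK2206 at 2.5 µM, 1.5 h before. The inhibitor of the second experiment is SB431542 in the sample titles and SB505124 in the table's columns and the protocol; both block the ALK5 kinase. The extraction text also mentions RNA of mouse embryonic stem cells, which no library title names.

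Per the file headers, the deposited 90 min table holds counts of reads per gene for 22166 genes, together with 5 lines of read totals that are not genes. The authors scaled the deposited 24 h table, whose signal is a normalized count per gene for 23337 genes. Division by 1 step per library turned 100% of its values into whole numbers within a tolerance of 0.001, and these were taken as recovered reads. The authors' notes name FastQC 0.11.3, Bowtie2, SAMtools 0.1.19, HTSeq 0.5.4 and DESeq2 with the mm10 build, without their settings. The library kit was unstranded, so overlapping and antisense genes were not separated. Gene positions came from the GRCm38 annotation, matched by symbol. At 90 min, 25 symbols had been turned into dates and were kept as they stood.

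Levels at 90 min are in CPM, the counts scaled to the library's gene reads with its TMM factor. Changes at 90 min were fitted with the edgeR 4.0.16 quasi-likelihood test on counts with TMM scaling and filterByExpr, which kept 12761 genes. Changes at 24 h were fitted with limma 3.58.1 (empirical Bayes with a trend) on log2(normalized count + 1) for the 12096 genes with a mean normalized count of at least 10. Each experiment had 1 model with a coefficient per group, so that its 8 libraries shared 1 estimate of the spread. The 9 comparisons were contrasts of these models. They comprised the TGFb response in each arm, the difference between the arms' responses, and Smad4RE against Vector under the inhibitor. Doxycycline against none was compared under TGFb and under the inhibitor. Genes were called at a Benjamini-Hochberg adjusted p below 0.05, two-sided. Errors of levels are SD over n = 2 libraries. Errors of log2 changes are model standard errors (SE) at 24 h. At 90 min they are the size of the log2 change over the square root of its F statistic, which only approximates an SE. For genes with few reads this approximation is rough. Levels were not compared between the 2 tables.

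Before the data were examined, 23 gene lists, the named-gene rule, the tests of the comparisons and all alternatives were fixed. The lists held direct Smad targets, BMP and Id targets, EMT transcription factors, epithelial junction and identity genes, mesenchymal and matrix genes, endoderm and pancreas progenitor factors, proapoptotic Bcl2 family genes, antiapoptotic genes, death receptors and caspases, immediate-early genes, cytostatic and cell-cycle inhibitor genes, cell cycle genes, interferon response genes, integrated stress response genes, mitochondrial-encoded genes, sterol synthesis genes, TGFb pathway components, cytokines, growth factors, and markers of 4 other cell types. Lists with at least 5 measured genes were tested against all other genes with camera (limma, preset correlation 0.01) and again with a correlation estimated from the residuals, on log-CPM with a prior count of 2 at 90 min. The fry test asked whether a list's genes moved, on balance, one way. Genes that rose or fell at 90 min in Smad4RE cells made 2 further lists for the 24 h comparisons.

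Named genes followed 3 rules: a fixed set (Smad4, Smad7, Skil, Snai1, Klf5, Sox4, Id1, Serpine1, Cdh1 and Bcl2l11 at 90 min, and Sox4, Snai1, Zeb1, Klf5, Cdh1, Vim, Bcl2l11, Bmf, Foxa1 and Id1 at 24 h); the 8 largest rises and falls of each main comparison, or 4 of the others, among called genes with separated groups and a mean of at least 1 CPM or 50 normalized counts; and 4 members of each list. Where all libraries of a group were at 0, the change is given as a lower bound from a floor of 3 reads over the group's 2 libraries. Floors cover counting error only. Intervals of medians and shares cover the spread between genes taken as independent, not the correlation between genes or the spread between cultures.

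The pipeline was tested on simulated data with 150 changed genes per fold size over 3 simulations. For the Smad4RE response it recovered 80.7% of genes changed 1.25-fold, 93.3% at 1.5-fold, 94.0% at 2-fold and 100% at 4-fold. For the difference between responses at 90 min it recovered 67.3%, 91.3%, 93.3% and 99.3%. For the 24 h response without doxycycline it recovered 33.3%, 86.0%, 98.0% and 99.3%, and for the difference at 24 h 5.33%, 60.7%, 92.0% and 97.3%. False calls made up 4.90%, 6.17%, 6.94% and 6.18% of the calls, and a list shifted by 0.5 log2 was called in 3 of 3 simulations for each. Over the 3 simulations, camera also made 2 calls among the 18 lists that were not shifted for the Smad4RE response. It made 2 for the difference at 90 min, and 0 among 17 for both at 24 h. Each simulation changed 200 genes, none with few reads, besides the shifted list, and gave each gene 1 spread in all groups. In the data far more genes were called and the 24 h libraries with inhibitor alone varied more. The rates may therefore be too favourable for the data.

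The alternatives at 90 min were DESeq2 1.42.0 size factors, library size alone, no filter, the DESeq2 Wald test, limma-trend, a replicate block, only the compared groups, and each library left out. At 24 h they were pseudocounts of 0.5 and 8, no filter, a mean of 50, quantile normalization, TMM on the deposited values, edgeR and DESeq2 on recovered reads, a replicate block, only the compared groups, and each library left out. Set tests were repeated with the estimated correlation, and early lists and shares with a log2 change of at least 1. Replicates share only a number, so no pairing entered the main models. Computations used R 4.3.3, and figures matplotlib 3.10.9 with numpy 2.4.6. The 6 chromatin libraries of the series were not analysed here.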

Results

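The data were 16 RNA-seq libraries of KSIC_c806 pancreatic cancer cells, in 8 groups of 2 replicates. The first experiment measured cells without (Vector) and with restored Smad4 (Smad4RE) after 90 min of TGFb or 2 h of a TGFb receptor inhibitor. The second measured Smad4-restored cells after 24 h of TGFb or inhibitor, without or with doxycycline, which induces an shRNA against Sox4. Reads assigned to genes at 90 min came to 34.5 M and 31.3 M in Vector with inhibitor, 38.1 M and 40.2 M in Vector with TGFb, 36.2 M and 26.2 M in Smad4RE with inhibitor, and 34.3 M and 32.4 M in Smad4RE with TGFb. At 24 h the recovered reads came to 23.6 M and 24.0 M with inhibitor alone, 23.9 M and 24.6 M with TGFb alone, 24.2 M and 24.3 M with doxycycline and inhibitor, and 22.2 M and 23.5 M with doxycycline and TGFb. The first principal component held 85.1% of the variance at 90 min and 76.4% at 24 h. The labels do not state whether replicates were separate cultures, so the p-values measure a spread between libraries that may be technical. No group received doxycycline with a control shRNA, and no group was left without both TGFb and inhibitor. Each TGFb response is therefore TGFb against inhibitor. In it, added TGFb cannot be told apart from effects of the inhibitor, such as block of signalling already present.

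Smad4, the shared mediator of TGFb receptor signals (chromosome 18, 73634790 to 73703791, GRCm38), was read in all libraries. Reads over the deleted part of the gene and over the restored construct were not examined, so these levels do not measure intact Smad4. It stood at 44.5 and 46.6 CPM in Vector with inhibitor and 44.8 and 45.4 CPM in Vector with TGFb. In Smad4RE cells it stood at 57.0 and 57.2 CPM with inhibitor and 59.6 and 61.1 CPM with TGFb. Under the inhibitor the 2 lines differed by a log2 change of 0.33 ± 0.0403 (adjusted p = 1.1e-07). At 24 h Smad4 read 718 and 829 normalized counts with inhibitor, 1279 and 1294 with TGFb, 704 and 756 with doxycycline and inhibitor, and 1041 and 973 with doxycycline and TGFb. Sox4, a transcription factor and the target of the shRNA (chromosome 13, 28948919 to 28953699), stood at 170 and 166 CPM in Vector with inhibitor, 257 and 240 CPM in Vector with TGFb, 237 and 244 CPM in Smad4RE with inhibitor, and 392 and 386 CPM in Smad4RE with TGFb. At 24 h Sox4 read 2423 and 3613 normalized counts with inhibitor, 13199 and 13552 with TGFb, 754 and 661 with doxycycline and inhibitor, and 3670 and 3470 with doxycycline and TGFb.

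The Smad4RE response at 90 min asked which genes differ early between TGFb and inhibitor when Smad4 is present. Snai1, a repressor of epithelial genes (chromosome 2, 167538195 to 167542814), rose 76.7-fold, from 0.474 ± 0.0262 to 36.9 ± 0.0549 CPM (SD, n = 2), a log2 change of 6.26 ± 0.124. Serpine1, which encodes a plasminogen activator inhibitor (chromosome 5, 137061504 to 137072272), rose 12.4-fold, from 164 ± 3.25 to 2035 ± 45.5 CPM. The feedback inhibitors Smad7 (chromosome 18, 75367365 to 75395935) and Skil (chromosome 3, 31095058 to 31122923) rose by 2.36 ± 0.0347 and 1.98 ± 0.0299 on the log2 scale. Sox4 rose from 241 ± 4.86 to 389 ± 4.19 CPM, a log2 change of 0.70 ± 0.0320. Klf5, a factor of epithelial progenitors (chromosome 14, 99298691 to 99313412), fell from 77.3 ± 3.91 to 48.3 ± 0.95 CPM, a log2 change of -0.68 ± 0.0449. Bcl2l11, which encodes the death activator Bim (chromosome 2, 128126038 to 128162547), rose from 47.8 ± 0.176 to 85.6 ± 1.96 CPM, a log2 change of 0.84 ± 0.0380. Bmf, another BH3-only death activator (chromosome 2, 118528757 to 118549686), rose from 1.47 ± 0.248 to 6.52 ± 0.669 CPM. The BMP target Id1 rose by 0.31 ± 0.0720 and Smad4 did not pass (0.08, adjusted p = 0.132). Cdh1, which encodes E-cadherin (chromosome 8, 106603350 to 106670247), passed at 0.10 ± 0.0295, but not without Smad4RE inhibitor replicate 1 (0.07), without Smad4RE TGFb replicate 1 (0.09) or with library size alone (0.03).

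**Figure D1:**
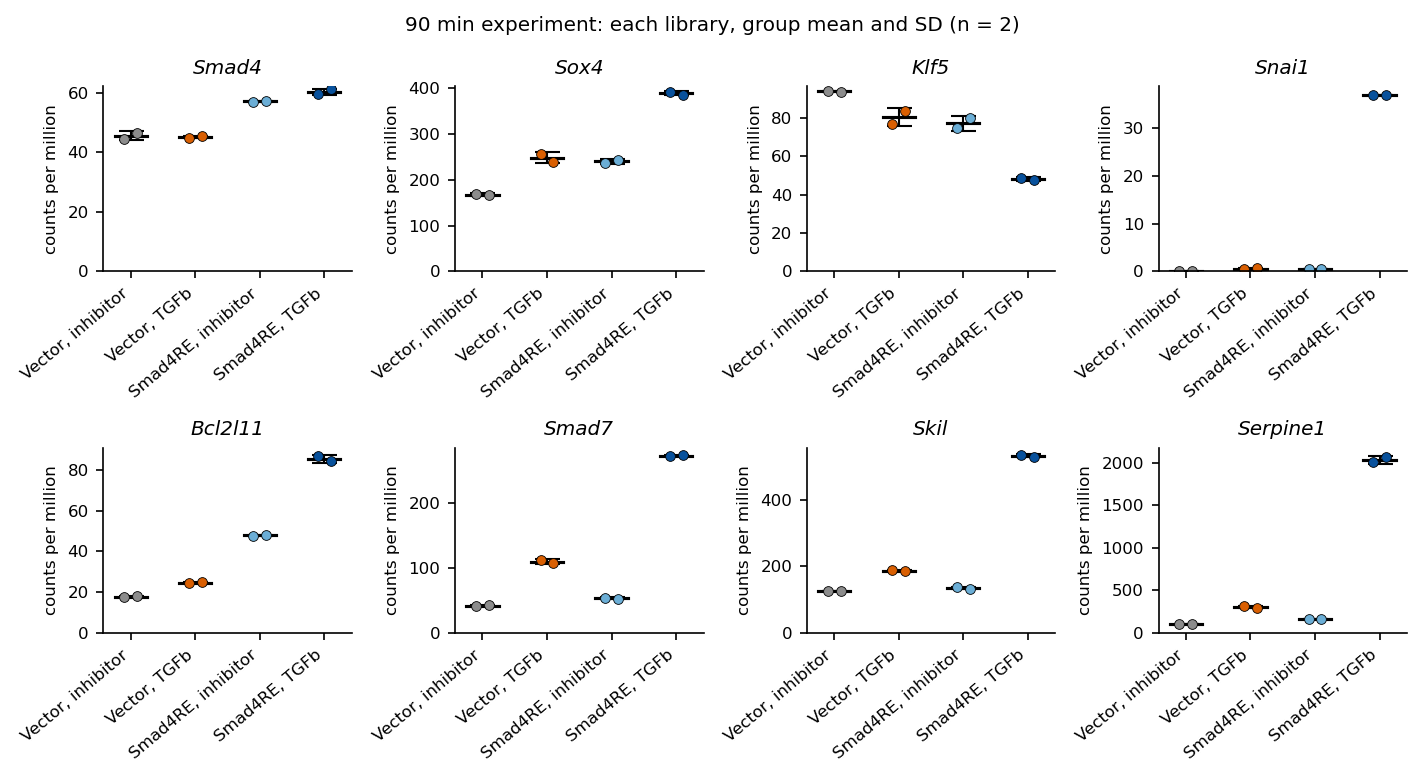
Levels of 8 genes in the 8 libraries at 90 min, in CPM, one point per library, with the mean and SD of each group of 2. Snai1 reached 36.9 CPM in Smad4RE cells with TGFb and 0.579 CPM in Vector cells with TGFb.

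The largest rises further included the tight junction gene Cldn4 (5.32), the growth factor gene Fgf18 (4.51) and the scavenger receptor gene Olr1 (5.23), all as log2 changes, and the cytokine gene Il11 rose 22.6-fold. Pdgfb (2.22), Vegfa (2.12), Jag1 (1.89) and Lif (1.72) encode secreted or surface ligands, and Sox9 (1.85) and Foxq1 (1.83) encode transcription factors. Falls included the chemokine gene Cxcl5 (-2.01), the signalling regulator Rgs2 (-1.98), the sulfotransferase gene Hs3st1 (-2.35) and the endoderm factor Foxa2 (-1.40). Of 24 direct Smad targets 22 rose and 2 fell (Cdkn2b and Rgs16), with the same counts adjusted over the list alone, a median of 1.00 and an adjusted p = 0.0120 with an estimated correlation. Of 37 growth factors 20 rose and 7 fell, the same adjusted over the list alone (adjusted p = 0.0442 with an estimated correlation). A further 5 lists passed at the preset correlation only. Mesenchymal genes rose in 20 and fell in 2 of 41 (20 and 3 adjusted over the list alone), EMT factors rose in 7 and fell in 2 of 13, epithelial genes rose in 18 and fell in 6 of 45, and TGFb components rose in 11 and fell in 2 of 25 (12 and 2 adjusted over the list alone), each with adjusted p = 0.128 with an estimated correlation. Immediate-early genes rose in 15 and fell in 8 of 25 (adjusted p = 0.187 with an estimated correlation). The proapoptotic list (4 rose and 1 fell of 11, median 0.04), the death receptor list (0 rose and 5 fell of 17) and the antiapoptotic list (1 rose and 3 fell of 9) did not pass in camera, at adjusted p = 0.0888, 0.120 and 0.276. Neither did cytostatic genes (4 rose and 4 fell of 13), BMP and Id targets (6 and 3 of 12), cytokines (9 and 4 of 18), endoderm factors (13 and 6 of 22), sterol genes (4 and 5 of 22) or interferon genes (3 and 5 of 23). The integrated stress response list did not pass in camera, with a median of -0.06 and a mean of 0.01. Fry, which does not compare a list with other genes, called 14 of the 19 lists, among them the proapoptotic, death receptor, antiapoptotic, cytostatic, BMP and Id, cytokine and endoderm lists. Of all 12761 genes 2202 rose and 1616 fell in edgeR, 313 and 79 of them at least 2-fold. With library size alone in place of TMM, 1533 rose and 3696 fell, so that rises made up 29.3% of calls against 57.7%, and with the DESeq2 Wald test 1623 rose and 838 fell.

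In Vector cells the same contrast asked what differs between TGFb and inhibitor without restored Smad4. Serpine1 rose 2.78-fold, from 109 ± 0.425 to 304 ± 14.5 CPM (SD, n = 2), a log2 change of 1.48 ± 0.0345. Smad7 rose by 1.39 ± 0.0373, the growth factor gene Ngf by 1.62 ± 0.0908 and the AP-1 subunit gene Junb by 1.62 ± 0.0291. Snai1 rose from 0.134 ± 0.0303 to 0.579 ± 0.159 CPM (log2 2.09 ± 0.428, adjusted p = 0.00142). Sox4 rose by 0.56 ± 0.0328, Skil by 0.56 ± 0.0305 and Bcl2l11 by 0.47 ± 0.0525, while Klf5 fell by 0.22 on the log2 scale (adjusted p = 0.000297). Id1 rose (0.39, adjusted p = 0.00147), but not without Vector TGFb replicate 2 (0.26). Cdh1 (0.06, adjusted p = 0.203) and Smad4 (-0.01, adjusted p = 0.896) did not pass. Falls included the C/EBP factor gene Cebpd (-1.26), the homeobox gene En1 (-0.78) and the Notch target Hes1 (-0.50). Of 24 Smad targets 16 rose and 1 fell (17 and 1 adjusted over the list alone; adjusted p = 0.00888 with an estimated correlation). The growth factor list (12 rose and 1 fell, 14 and 1 adjusted over the list alone), the epithelial list (13 and 1, 13 and 2 adjusted over the list alone), the mesenchymal list (9 and 1, 12 and 1 adjusted over the list alone) and the sterol list (7 and 0, 10 and 1 adjusted over the list alone) passed at the preset correlation, with adjusted p = 0.0688, 0.114, 0.291 and 0.382 with an estimated correlation. Cytostatic genes (3 rose and 1 fell, 5 and 2 adjusted over the list alone) also did (adjusted p = 0.382 with an estimated correlation). So did 3 lists that a single library decided. Integrated stress response genes (2 rose and 14 fell of 27, 5 and 16 adjusted over the list alone, median -0.12, adjusted p = 0.509 with an estimated correlation) did not pass without Vector inhibitor replicate 1 (-0.07) or Vector TGFb replicate 1 (-0.06). Cell cycle genes (6 rose and 0 fell of 46, 7 and 0 adjusted over the list alone, adjusted p = 0.565 with an estimated correlation) did not pass without Vector inhibitor replicate 1 (median 0.0040). Proapoptotic genes (3 rose and 1 fell of 11, 5 and 1 adjusted over the list alone, adjusted p = 0.382 with an estimated correlation) did not pass without Vector inhibitor replicate 1 or Vector TGFb replicate 2 (0.05 each). In all, 767 genes rose and 428 fell, 43 and 4 of them at least 2-fold, and library size alone gave 613 and 636 (rises 49.1% against 64.2%). The DESeq2 Wald test gave 534 and 135. Fry called 13 of the 19 lists. Without Vector inhibitor replicate 1 the counts were 495 and 179, and without Vector TGFb replicate 1 they were 499 and 170.

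The difference between the responses, tested as an interaction, asked which early changes differed between cells with and without restored Smad4. Under the inhibitor 8415 of 12761 genes (65.9%) differed between the lines. Restored Smad4 therefore cannot be told apart here from other differences between the lines. The response of Snai1 was larger in Smad4RE than in Vector cells by 4.17 ± 0.708 on the log2 scale. Snai1 had 9 reads over the 2 Vector libraries with inhibitor. Fgf18 responded more by 4.21 ± 0.280, the immediate-early gene Arc by 3.58 ± 0.231 and Il11 by 3.33 ± 0.506. Serpine1 responded more by 2.16 ± 0.0477, the integrin gene Itga5 by 1.98 ± 0.0483, Vegfa by 1.98 ± 0.0556, Skil by 1.42 ± 0.0425, Sox9 by 1.40 ± 0.190 and Smad7 by 0.97 ± 0.0520. Bcl2l11 responded more by 0.37 ± 0.0654 (adjusted p = 0.000156), and Zeb1, an EMT factor (chromosome 18, 5591327 to 5775468), by 0.43 ± 0.0572. Klf5 (-0.45 ± 0.0599, adjusted p = 2.9e-06), Cxcl5 (-1.80 ± 0.0827) and Foxa2 (-1.23 ± 0.0587) had lower log2 changes, since they fell further in Smad4RE than in Vector cells. Sox4 did not pass (0.13 ± 0.0458, adjusted p = 0.0582), but did without Vector TGFb replicate 1 (0.18). Smad4 (0.09, adjusted p = 0.334), Cdh1 (0.03, adjusted p = 0.690) and Id1 (-0.09, adjusted p = 0.699) did not pass either.

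**Figure D2:**
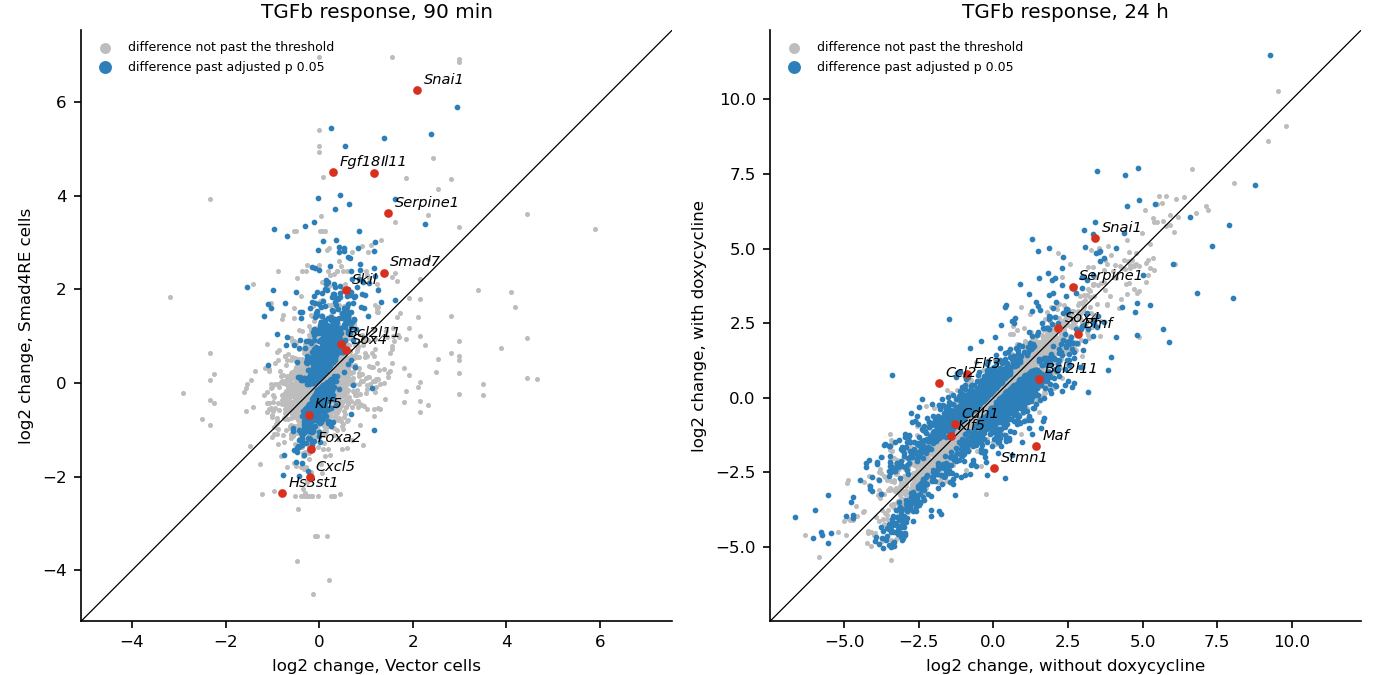
Log2 change with TGFb of each tested gene in a pair of arms, Vector against Smad4RE at 90 min and without against with doxycycline at 24 h; blue points passed the test of the difference, red points carry names, and the line marks equal responses. Snai1 changed by 2.09 in Vector and 6.26 in Smad4RE cells.

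In these list counts more and less mean a higher and a lower signed log2 change. A gene that fell further in Smad4RE cells counts as less. Of the 24 direct Smad targets 20 responded more in Smad4RE cells and 1 less, Cdkn2b (21 and 1 adjusted over the list alone). Their median difference was 0.63, with adjusted p = 0.0117 with an estimated correlation. Growth factors responded more in 14 and less in 2 of 37 (14 and 5 adjusted over the list alone, adjusted p = 0.0481 with an estimated correlation). At the preset correlation 8 more lists passed. Immediate-early genes (13 more and 6 less, 14 and 8 adjusted over the list alone), mesenchymal genes (15 and 0, 16 and 2 adjusted over the list alone) and endoderm factors (10 and 4, 11 and 4 adjusted over the list alone) each had adjusted p = 0.199 with an estimated correlation. TGFb components (8 and 2, the same adjusted over the list alone) had adjusted p = 0.178 with an estimated correlation. Sterol synthesis genes had a higher change in 0 and a lower one in 8 of 22 (0 and 9 adjusted over the list alone). Their median was -0.09, with adjusted p = 0.303 with an estimated correlation. Ldlr (-0.30) and Stard4 (-0.33) were among them. Ldlr fell further in Smad4RE cells, from 294 to 230 CPM, than in Vector cells, from 379 to 365 CPM. EMT factors (4 and 2, 5 and 2 adjusted over the list alone, adjusted p = 0.199 with an estimated correlation) did not pass without Smad4RE TGFb replicate 2 (0.13) or Vector TGFb replicate 1 (0.09). Cytokines (6 and 3, 8 and 3 adjusted over the list alone, median 0.43, adjusted p = 0.204 with an estimated correlation) did not pass without Smad4RE inhibitor replicate 2 (0.34), Smad4RE TGFb replicate 2 (0.41) or Vector TGFb replicate 1 (0.29). Stress response genes (4 and 1, 6 and 2 adjusted over the list alone, median 0.08, adjusted p = 0.603 with an estimated correlation) did not pass without Smad4RE inhibitor replicate 1 (0.07), Smad4RE TGFb replicate 2 (0.07), Vector inhibitor replicate 1 (0.04) or Vector TGFb replicate 1 (0.0045). Fry called 11 of the 19 lists. In edgeR 1127 genes responded with a higher change in Smad4RE cells and 578 with a lower one, and library size alone gave 832 and 1118 (rises 42.7% against 66.1%). The DESeq2 Wald test gave 737 and 296. Of the 2202 genes that rose in Smad4RE cells, 1065 (48.4%) rose by more there than in Vector cells and 9 by less. Of the 1616 that fell, 509 (31.5%) fell by more and 0 by less. In 20 simulations with equal responses the share that rose by more was at most 0.102%. When no gene differs, the adjusted threshold leaves almost no call. The simulated share therefore bears only on equal responses of all genes, and is not the share of false calls among the 1065. Genes that responded only in Vector cells were not counted in these shares. Vector cells shared 613 of their 767 rises (79.9%) and 228 of their 428 falls (53.3%) with Smad4RE cells, against 132 and 54.2 from independent sets.

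Under the inhibitor, given for 2 h, the comparison asked how the lines differed without added TGFb. The matrix gene Col6a1 was higher in Smad4RE cells by 7.60 ± 0.226 on the log2 scale, Sox9 by 3.41 ± 0.111, Id3 by 4.01 ± 0.202 and the forkhead factor gene Foxa1 (chromosome 12, 57540628 to 57548029) by 2.80 ± 0.0807. Bcl2l11 stood at 47.8 ± 0.176 CPM against 17.8 ± 0.247 CPM in Vector cells (SD, n = 2), a difference of 1.43 ± 0.0485. The protease inhibitor gene Spint1 (-5.10 ± 0.171), the tight junction genes Ocln (-3.20 ± 0.107) and Tjp3 (-2.42 ± 0.0852) and the mucin gene Muc1 (-2.77 ± 0.0502) were lower. Fam167a was at least 70.6-fold higher, and Gulp1, Pcsk5, Prdm16 and Cxcl12 were at least 168-fold, 112-fold, 84.3-fold and 7.59-fold lower, with both inhibitor libraries of 1 line at 0 reads. Nrn1 stood at 35.2 against 0.0297 CPM and Homer2 at 0.0517 against 86.3 CPM. Epithelial genes were higher in 7 and lower in 37 of 45 (median -0.57) and EMT factors higher in 12 and lower in 0 of 13 (median 0.57), each the same adjusted over the list alone. The first had adjusted p = 0.0738 and the second adjusted p = 0.0813 with an estimated correlation. Sterol genes (21 higher, 1 lower), cell cycle genes (36 and 4, 38 and 4 adjusted over the list alone), stress response genes (5 and 18), Smad targets (16 and 4), TGFb components (16 and 5) and mesenchymal genes (23 and 13) passed at the preset correlation, with adjusted p = 0.256, 0.455, 0.563, 0.219, 0.219 and 0.455 with an estimated correlation. Fry called 14 of the 19 lists. In all 4161 genes were higher and 4254 lower, 886 and 716 at least 2-fold. Genes on chromosome 15 had a median difference of 0.36 (quartiles 0.12 to 0.61, 466 genes), and the next highest chromosome median was 0.06 on chromosome 19.

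**Figure D3:**
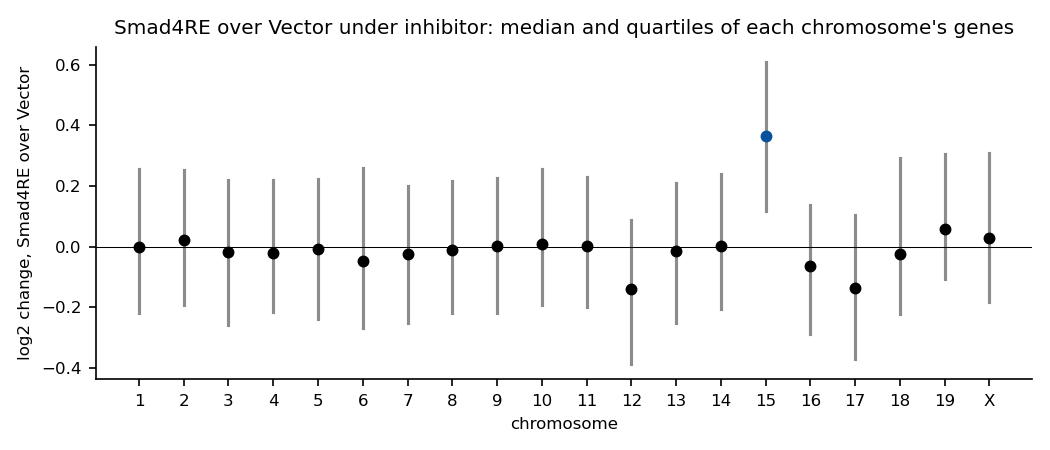
Median and quartiles of the log2 difference between Smad4RE and Vector cells under the inhibitor, for the genes of each chromosome. Chromosome 15 had a median of 0.36 and chromosomes 12 and 17 medians of -0.14.

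At 24 h without doxycycline the TGFb response was measured in cells that kept Sox4. Sox4 rose 4.52-fold, from 3018 ± 842 to 13376 ± 249 normalized counts (SD, n = 2), a log2 change of 2.18 ± 0.149. Bcl2l11 rose from 500 ± 20.7 to 1432 ± 6.09 normalized counts (1.52 ± 0.0843) and Bmf from 107 ± 6.43 to 768 ± 23.1 (2.83 ± 0.136). Pmaip1, which encodes the death activator Noxa, rose by 1.38 ± 0.0558, and the survival gene Bcl2l1 fell by 0.66 on the log2 scale. Snai1 rose from 5.80 ± 1.35 to 70.9 ± 3.91 normalized counts (3.42 ± 0.283), Zeb1 by 0.72 ± 0.105 and Zeb2 by 1.53 ± 0.105. Cdh1 (-1.28 ± 0.0707), Klf5 (-1.42 ± 0.126), the ductal keratin genes Krt19 (-2.02 ± 0.0570) and Krt7 (-1.82 ± 0.0616), and Id1 (-4.22 ± 0.0710) fell. Vim, the mesenchymal filament gene (chromosome 2, 13574311 to 13582826), fell by 0.32 on the log2 scale. Foxa1 did not pass (0.23, adjusted p = 0.128), but did without the replicate 2 library with inhibitor alone (0.42). The matrix genes Fn1 (4.32 ± 0.139) and Thbs1 (4.79 ± 0.119) rose, and the hyaluronan synthase gene Has2 was at least 404-fold higher. Il11 (9.28 ± 0.286) and Cldn4 (9.52 ± 0.396) rose from 7.25 ± 2.02 and 5.81 ± 1.39 normalized counts. Large falls included the aldehyde dehydrogenase gene Aldh1a1 (-5.76 ± 0.147), the water channel gene Aqp1 (-5.54 ± 0.124) and the chemokine gene Ccl20 (-5.84 ± 0.170).

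**Figure D4:**
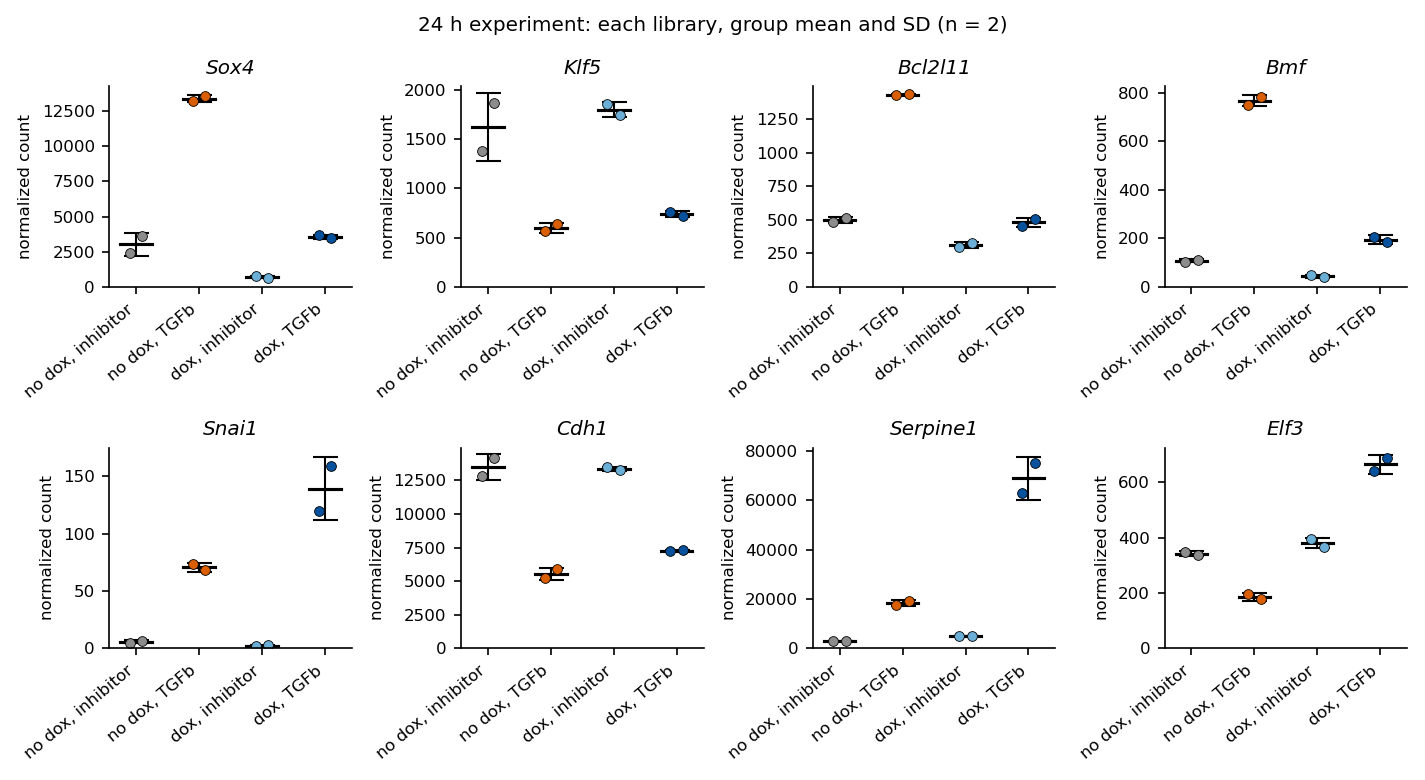
Levels of 8 genes in the 8 libraries at 24 h, in normalized counts, one point per library, with the mean and SD of each group of 2. Bcl2l11 stood at 1432 with TGFb alone and 482 with doxycycline and TGFb.

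All 46 cell cycle genes fell (median -2.96, 46 adjusted over the list alone), Ccna2 (-3.83), Tk1 (-4.21) and Rrm2 (-3.17) among them, with adjusted p = 0.0209 with an estimated correlation. At the preset correlation 5 other lists passed. Smad targets rose in 22 and fell in 0 of 24 (the same adjusted over the list alone, median 1.09, adjusted p = 0.345 with an estimated correlation), and sterol genes rose in 0 and fell in 20 of 23 (1 and 20 adjusted over the list alone, adjusted p = 0.351 with an estimated correlation). Mesenchymal genes (20 rose and 7 fell of 32, 21 and 7 adjusted over the list alone), TGFb components (15 and 3 of 23, 16 and 3 adjusted over the list alone) and EMT factors (9 and 2 of 11, the falls being Snai3 and Twist1) each had adjusted p = 0.532 with an estimated correlation. Proapoptotic genes (6 rose and 3 fell of 11, 7 and 4 adjusted over the list alone, median 0.36) did not pass in camera (adjusted p = 0.116), nor did endoderm factors (5 and 14 of 22) or interferon genes (2 and 9 of 18). The epithelial list did not pass in camera (15 rose and 21 fell of 42), with a median of -0.25 and a mean of 0.02. Cytokines had a median of -0.55 and a mean of 0.08, and antiapoptotic genes a median of 0.12 and a mean of -0.40, neither passing in camera. Fry called all 18 lists, epithelial genes, cytokines, endoderm factors, interferon genes and antiapoptotic genes downwards and proapoptotic genes upwards. Of 12096 genes 4150 rose and 4069 fell in limma, 1021 and 1482 of them at least 2-fold, and edgeR on recovered reads called 8191 of these 8219, none in the opposite direction.

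With doxycycline, the TGFb response was measured in cells with the Sox4 shRNA induced. Sox4 rose from 707 ± 66.0 to 3570 ± 142 normalized counts (SD, n = 2). Snai1 rose from 2.45 ± 0.683 to 139 ± 27.5 normalized counts (5.35 ± 0.283), Fn1 by 4.36 ± 0.139, Thbs1 by 4.85 ± 0.119, Sox9 by 4.90 ± 0.158 and Serpine1 by 3.72 ± 0.0836. Bmf rose from 44.1 ± 7.11 to 195 ± 17.0 normalized counts and Bcl2l11 from 314 ± 20.9 to 482 ± 34.9. Pmaip1 rose by 0.53 ± 0.0558 and Bcl2l1 fell by 0.80 on the log2 scale. Klf5 fell from 1798 ± 73.9 to 738 ± 31.3 and Cdh1 from 13361 ± 155 to 7279 ± 40.7 normalized counts. Id1 (-4.52 ± 0.0710), Id3 (-3.96 ± 0.0802), Krt19 (-1.50 ± 0.0570) and the immediate-early gene Fos (-2.64 ± 0.0699) fell, and Has2 was at least 262-fold higher. All 46 cell cycle genes fell (median -3.38, 46 adjusted over the list alone, adjusted p = 0.0136 with an estimated correlation). Smad targets rose in 23 and fell in 0 of 24 (24 and 0 adjusted over the list alone, adjusted p = 0.241 with an estimated correlation). Mesenchymal genes (19 rose and 6 fell, 19 and 7 adjusted over the list alone), proapoptotic genes (7 and 0 of 11), stress response genes (5 and 16 of 27) and EMT factors (8 and 2 of 11) passed at the preset correlation, each with adjusted p = 0.486 with an estimated correlation. Fry called 17 of the 18 lists. In all 3570 genes rose and 3586 fell, 735 and 1308 at least 2-fold, and edgeR on recovered reads called 7093 of the 7156. Of the rises 2827 (79.2%) also rose without doxycycline and of the falls 2926 (81.6%) also fell, against 1225 and 1206 from independent sets.

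The difference between these responses, tested as an interaction, asked which changes differed with doxycycline, which induces the Sox4 shRNA. Without a control shRNA it cannot tell Sox4 apart from doxycycline. Sox4 with doxycycline and TGFb (3570 ± 142 normalized counts) was also not below its level with inhibitor alone (3018 ± 842). The TGFb response of Bcl2l11 was lower with doxycycline by -0.90 ± 0.119 on the log2 scale (adjusted p = 0.00124). The AP-1 genes Fosb (-2.60 ± 0.167) and Fos (-1.54 ± 0.0989), the tubulin regulator gene Stmn1 (-2.38 ± 0.121) and the adhesion gene Igsf9 (-2.53 ± 0.109) also responded lower. Higher responses with doxycycline were those of the epithelial factor gene Elf3 (1.67 ± 0.132) and the intestinal factor gene Cdx2 (1.19 ± 0.11). The chemokine genes Ccl2 (2.31 ± 0.184) and Cxcl5 (1.86 ± 0.190) also responded higher. Here and for the lists higher and lower are signed, so a smaller fall with doxycycline counts as higher and a larger one as lower. By group means Cdx2 and Cxcl5 fell less with doxycycline and Fos fell further. Snai1 responded higher (1.93 ± 0.400, adjusted p = 0.00885), but did not pass without the replicate 2 library with doxycycline and TGFb (1.73) or with DESeq2 on recovered reads (2.22). Bmf responded lower (-0.70 ± 0.192, adjusted p = 0.0284), but did not pass without any 1 of 5 libraries: TGFb alone replicate 1 (-0.73) or 2 (-0.67), doxycycline with inhibitor replicate 1 (-0.54), or doxycycline with TGFb replicate 1 (-0.79) or 2 (-0.61). Cdh1 responded higher (0.41 ± 0.10, adjusted p = 0.0180) but did not pass without TGFb alone replicate 1 (0.32), doxycycline with inhibitor replicate 1 (0.42) or 2 (0.40), or doxycycline with TGFb replicate 1 (0.41) or 2 (0.40). Neither Sox4 (0.16 ± 0.211, adjusted p = 0.613) nor Klf5 (0.14 ± 0.179, adjusted p = 0.612) passed. Without inhibitor alone replicate 1 both passed (0.45 and 0.36), and without its replicate 2 they were -0.13 and -0.08. Zeb1 (-0.45, adjusted p = 0.0582), Id1 (-0.30, adjusted p = 0.0563) and Foxa1 (-0.53, adjusted p = 0.0598) did not pass. Without inhibitor alone replicate 1 Zeb1 (-0.26) and Id1 (-0.36) passed, without its replicate 2 Zeb1 (-0.63), Id1 (-0.25) and Foxa1 (-0.72) did, and with DESeq2 on recovered reads Zeb1 (-0.43) did. Vim passed (0.31, adjusted p = 0.0406), but not without any 1 of the 6 libraries other than those with inhibitor alone (0.26 to 0.35), nor with no filter (adjusted p = 0.103).

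Cell cycle genes responded lower in 31 of 46 (32 adjusted over the list alone, median -0.64) and higher in 0, and immediate-early genes lower in 15 of 24 (15 adjusted over the list alone, median -0.36) and higher in 0, each with adjusted p = 0.0526 with an estimated correlation. Sterol genes responded higher in 14 of 23 (19 adjusted over the list alone, adjusted p = 0.159 with an estimated correlation) and lower in 0. Stress response genes (2 higher, 11 lower, 2 and 13 adjusted over the list alone), cytokines (7 higher, 1 lower, 9 and 1 adjusted over the list alone) and endoderm factors (9 higher, 2 lower, 11 and 4 adjusted over the list alone) passed at the preset correlation, each with adjusted p = 0.318 with an estimated correlation. The last did not pass without inhibitor alone replicate 2 (0.18). Smad targets did not pass in camera (7 higher, 6 lower, median -0.06, mean 0.16, adjusted p = 0.997), nor did proapoptotic genes (3 and 3, 4 and 3 adjusted over the list alone, median 0.17, mean -0.08, adjusted p = 0.997). Fry called 12 of the 18 lists. In limma 1354 genes responded higher with doxycycline and 1344 lower. Without inhibitor alone replicate 1 the counts were 2189 and 1997, and without its replicate 2 they were 2667 and 2999. They were 676 and 732 without TGFb alone replicate 1, 800 and 741 without its replicate 2, 624 and 689 without doxycycline with inhibitor replicate 1, 597 and 699 without its replicate 2, 859 and 888 without doxycycline with TGFb replicate 1, and 586 and 728 without its replicate 2. Of 4150 genes that rose without doxycycline 870 (21.0%) rose by more there and 170 (4.10%) by less, and of 4069 that fell 998 (24.5%) fell by more there and 282 (6.93%) by less. In 20 simulations with equal responses the share that rose by more was at most 0.0521%. These gave each gene 1 spread in all groups, but the libraries with inhibitor alone varied more (chi-square per degree of freedom 24.2 against 1.71 to 3.32). The simulated share may therefore be too low. Genes were chosen by their response without doxycycline, so those that responded only with doxycycline were not counted.

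**Figure D5:**
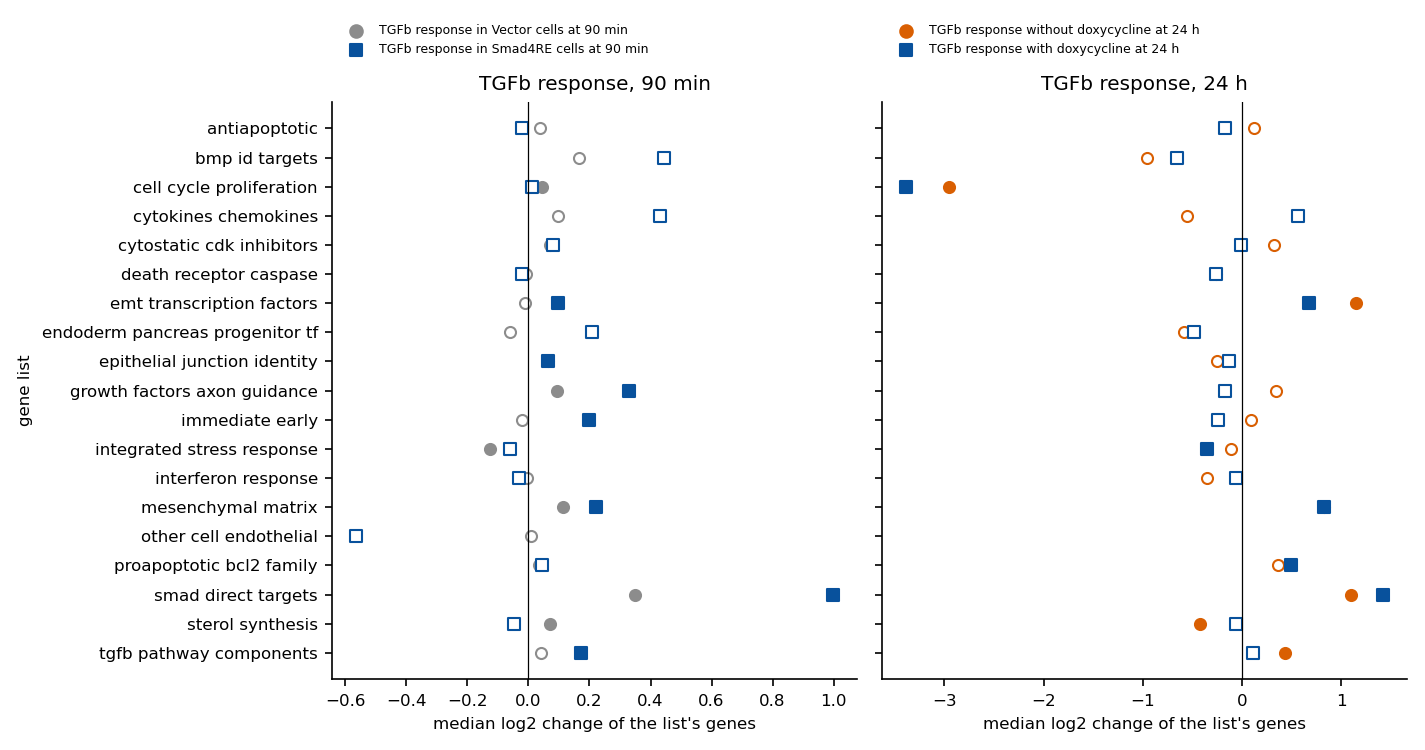
Median log2 change with TGFb of each gene list in each arm, at 90 min (Vector, Smad4RE) and 24 h (without and with doxycycline); filled symbols passed the set test at the preset correlation and open ones did not. Cell cycle genes had medians of -2.96 without and -3.38 with doxycycline.

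Under TGFb, doxycycline against none asked what doxycycline, which induces the shRNA, moved. Sox4 fell from 13376 ± 249 to 3570 ± 142 normalized counts (SD, n = 2), a log2 change of -1.91 ± 0.149. Bcl2l11 (-1.57 ± 0.0843) and Bmf (-1.97 ± 0.136) fell, as did the Hippo pathway factor gene Tead2 (-4.21 ± 0.0949), the actin regulator gene Marcksl1 (-4.19 ± 0.0904), the semaphorin receptor gene Plxnb1 (-4.76 ± 0.216) and the claudin gene Cldn6 (-1.54 ± 0.0681). Rises included Serpinb1a (4.32 ± 0.152), Serpine1 (1.90 ± 0.0836), Elf3 (1.83 ± 0.0930), the endoderm factor gene Hnf4a (1.22 ± 0.0872), Krt19 (0.99 ± 0.0570) and Cdh1 (0.39 ± 0.0707). Id1 did not pass (0.01, adjusted p = 0.944). Klf5 (0.30, adjusted p = 0.0686), Zeb1 (-0.27, adjusted p = 0.0580), Vim (0.12, adjusted p = 0.163) and Foxa1 (-0.23, adjusted p = 0.149) did not pass either, but all 4 did without inhibitor alone replicate 1 or replicate 2, at the same log2 changes. Snai1 rose (0.95, adjusted p = 0.0179), but not without TGFb alone replicate 1 (1.01) or 2 (0.90) or doxycycline with TGFb replicate 2 (0.75). Cell cycle genes fell in 38 of 46 (39 adjusted over the list alone, median -0.88, adjusted p = 0.0492 with an estimated correlation). Sterol genes rose in 19 of 23 (19 adjusted over the list alone) and epithelial genes rose in 24 and fell in 5 of 42 (24 and 5 adjusted over the list alone), each with adjusted p = 0.249 with an estimated correlation. Immediate-early genes (4 rose and 14 fell, 4 and 16 adjusted over the list alone) and stress response genes (4 and 18, the same adjusted over the list alone) passed at the preset correlation, with adjusted p = 0.214 and 0.455 with an estimated correlation. Cytostatic genes (1 rose and 8 fell, 1 and 9 adjusted over the list alone, adjusted p = 0.370 with an estimated correlation) did not pass without TGFb alone replicate 1 (-0.19) or doxycycline with TGFb replicate 1 (-0.22). Endoderm factors (12 rose and 3 fell, adjusted p = 0.474 with an estimated correlation) did not pass without inhibitor alone replicate 1 (0.31) or 2 (0.30) or doxycycline with TGFb replicate 1 (0.33). Fry called 13 of the 18 lists. In all 3223 genes rose and 3113 fell, 474 and 660 at least 2-fold, and edgeR on recovered reads called 6184 of the 6336.

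Under the inhibitor, the same contrast asked what doxycycline moved without TGFb. Sox4 fell from 3018 ± 842 to 707 ± 66.0 normalized counts (SD, n = 2), a log2 change of -2.07 ± 0.149. Tead2 (-2.58 ± 0.0949), Marcksl1 (-3.16 ± 0.0904), Plxnb1 (-3.39 ± 0.216), Sox9 (-1.54 ± 0.158), Bmf (-1.27 ± 0.136) and Bcl2l11 (-0.67 ± 0.0843) fell. The guanylate-binding protein gene Gbp8 rose to 406 ± 2.35 normalized counts (4.67 ± 0.290), and Ccl20 rose by 2.71 ± 0.170 and Fosb by 1.17 ± 0.118. Il11 stood at 0.491 ± 0.695 against 7.25 ± 2.02 normalized counts. Cell cycle genes fell in 26 of 46 (30 adjusted over the list alone, median -0.28, adjusted p = 0.143 with an estimated correlation) and epithelial genes rose in 17 and fell in 4 of 42 (19 and 4 adjusted over the list alone, adjusted p = 0.470 with an estimated correlation). EMT factors fell in 5 of 11 (5 adjusted over the list alone, adjusted p = 0.552 with an estimated correlation) but did not pass without inhibitor alone replicate 2 (-0.09). Interferon genes rose in 7 and fell in 0 of 18 without passing in camera (adjusted p = 0.158). Fry called 7 of the 18 lists. In all 2054 genes rose and 1805 fell, 176 and 212 at least 2-fold, and edgeR on recovered reads called 3787 of the 3859 and DESeq2 2897. Fitted on only the compared groups, 1160 rose and 1011 fell, with 2110 of the calls kept. Without inhibitor alone replicate 2 the counts were 3281 and 2872, and without doxycycline with inhibitor replicate 1 or 2 they were 814 and 748 or 976 and 883.

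The early genes were looked up in the 24 h experiment, with 11800 genes tested in both experiments. These were separate experiments and not a time course. The 24 h cells carried the Sox4 shRNA construct and all received MK2206, and serum differed too. A lasting change therefore cannot be told apart from these differences. Of 2123 genes that rose at 90 min in Smad4RE cells, 1317 also rose at 24 h without doxycycline, against 728 from independent sets, and 345 fell. Of 1580 that fell early 842 also fell, against 537, and 311 rose. With doxycycline 1280 and 907 moved the same way and 256 and 179 the opposite way. As sets, the early rises (median 0.40 without and 0.35 with doxycycline) and early falls (-0.31 and -0.37) passed in both arms at the preset correlation, and with an estimated correlation the adjusted p was 0.116, 0.0800, 0.0678 and 0.0258. Of 257 genes that rose at least 2-fold early 219 rose at 24 h without doxycycline and 16 fell. Neither set passed in camera or fry, which ask for a shift one way, in the test of the difference between the arms at 24 h. Genes of both sets were called in both directions there more often than independent sets give. The sets were chosen as called genes, and the expected numbers were not matched for expression level. The excess therefore cannot be told apart from genes that are easier to call. Of the early rises 337 responded higher with doxycycline, against 240, and 289 lower, against 239. Of the early falls 219 responded higher, against 179, and 237 lower, against 178.

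Other cell types were followed by marker lists. The highest group means at 90 min were 2.83 CPM among fibroblast markers (Pdgfra), 4.57 CPM among leukocyte markers (Csf1r), 5.43 CPM among endothelial markers (Egfl7) and 5.38 CPM among acinar and islet markers (Cela1). Csf1r stood at 4.33 and 4.57 CPM in Smad4RE cells and 0.092 and 0.10 CPM in Vector cells, with inhibitor and TGFb. At 24 h the highest group means were 61.1 (Pdgfra), 119 (Cd68), 246 (Egfl7) and 384 (Cela1) normalized counts. Endothelial markers did not pass as a list in camera in Smad4RE cells with TGFb (1 rose and 0 fell of 6, adjusted p = 0.740). None of the 13 mitochondrial-encoded genes was measured.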

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

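None of the tests in this part was chosen after its result was seen, but Pmaip1, Bax, Bid and Bok were added then, to show all called members of their list. The interaction test at 90 min singled out 1127 genes with a higher TGFb response in Smad4RE than in Vector cells and 578 with a lower one, and the test at 24 h 1354 genes with a higher TGFb response with doxycycline than without and 1344 with a lower one. The called genes given here, as differences of log2 changes, are the fixed ones, the largest each way and up to 2 of each list past the threshold in camera. These differences are signed, so a gene that fell further in Smad4RE cells, or with doxycycline, has a lower response there. Other called genes of the named-gene rule are not given.

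At 90 min the response was higher in Smad4RE cells for growth factor and cytokine genes, namely Fgf18 (4.21), Il11 (3.33), Vegfa (1.98), Csf1 (1.56), Pdgfb (1.53) and Lif (1.39). It was higher for the transcription factor genes Snai1 (4.17), Onecut3 (3.20), Fosb (2.02), Sox9 (1.40), Jun (1.09), Foxq1 (1.09), Cebpb (0.45) and Zeb1 (0.43). Genes of matrix, adhesion and its control were Has2 (3.99), Serpine1 (2.16), Itga5 (1.98) and Thbs1 (0.69), and genes of TGFb signalling were Skil (1.42), Smad7 (0.97), Tgfbr1 (0.78) and Acvr1 (0.67). Others were Olr1 (3.84), Arc (3.58), Fgfr1 (2.97), Ddit4 (0.84) and the death activator gene Bcl2l11 (0.37). The response was lower for the factor genes Foxa2 (-1.23) and Klf5 (-0.45), the chemokine genes Cxcl5 (-1.80) and Ccl20 (-1.24), the sterol genes Stard4 (-0.33) and Ldlr (-0.30), and Hs3st1 (-1.57), Rgs2 (-1.54), Map3k13 (-1.34), Exph5 (-1.27) and Pla2r1 (-1.22). Has2 and Olr1 did not pass without Vector inhibitor replicate 2 (3.16 and 2.82), and Fgfr1 did not without Vector inhibitor replicate 1 (2.83). Several of these differences rest on few reads over the 2 libraries of the lowest group. Vector cells with inhibitor had 7 reads of Has2, 8 of Olr1 and 9 of Snai1. Fgfr1 had 4 in Vector cells with TGFb, and Onecut3 had 4 in Smad4RE cells with inhibitor. Onecut3 stood at 1.72 and 2.67 CPM in Vector cells and 0.0548 and 0.948 CPM in Smad4RE cells, with inhibitor and TGFb.

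At 24 h the response was higher with doxycycline for the factor genes Snai1 (1.93), Elf3 (1.67) and Cdx2 (1.19), the chemokine genes Ccl2 (2.31) and Cxcl5 (1.86), the sterol genes Pcsk9 (1.01) and Mvd (0.54), and Cdh1 (0.41) and Vim (0.31). Of the proapoptotic list, 3 genes were higher, Bok (0.39), Bax (0.39) and Bid (0.33), and 3 were lower. The response was also higher for Trpm5 (4.15), Prg4 (3.19), Myh15 (3.03), Serpina3h (2.86), Apoc2 (2.67), Trim54 (2.33) and Leprel1 (2.33). It was lower for the death activator genes Bcl2l11 (-0.90), Pmaip1 (-0.86) and Bmf (-0.70), the cell cycle genes Ccna2 (-1.05) and Mcm7 (-0.84), the stress response genes Chac1 (-1.30) and Mthfd2 (-0.92), and the AP-1 genes Fosb (-2.60) and Fos (-1.54). It was also lower for Iglon5 (-4.67), Maf (-3.04), Glipr2 (-2.98), Rem2 (-2.71), Igsf9 (-2.53), Mex3b (-2.42) and Stmn1 (-2.38). Trpm5 and Myh15 had 0 reads with doxycycline and inhibitor and Iglon5 had 0 reads with inhibitor alone, so their differences depend on the added count of 1, and Serpina3h had 1 read with doxycycline and inhibitor.

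Apoc2 did not pass without doxycycline with inhibitor replicate 2 (2.47) or doxycycline with TGFb replicate 2 (2.36). Snai1 did not pass without doxycycline with TGFb replicate 2, nor Bmf and Cdh1 without any 1 of the libraries named for them in the Results. Bax (0.35 to 0.43) and Bid (0.31 to 0.34) did not pass without any 1 of the 6 libraries other than those with inhibitor alone, and this was not run for Bok. Vim did not pass without TGFb alone replicate 1 (0.35) or 2 (0.26), doxycycline with inhibitor replicate 1 (0.29) or 2 (0.32), or doxycycline with TGFb replicate 1 (0.32) or 2 (0.29). With edgeR on recovered reads Iglon5, Myh15, Prg4, Rem2 and Serpina3h did not pass, and with DESeq2 Myh15, Rem2, Serpina3h and Snai1 did not.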

How the results depend on the processing

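All alternatives in this part were fixed before the results were seen, and none of the tests was chosen afterwards. With each library left out in turn, 119 of 144 counts of called genes stayed within 1.5 times the reported count, 475 tests of lists past the threshold kept their call and 21 lost it, and 5914 tests of named genes kept theirs, while 192 became weaker and 17 stronger. A library left alone in its group was assumed to vary like the other groups. Under the other settings 126 counts stayed and 8 moved, and 295 tests of lists past the threshold kept their call and 3 lost it. There 5628 tests of named genes kept their call, with 84 weaker and 9 stronger. A replicate block moved 0 of 18 counts of called genes and kept 760 of 766 calls of named genes (4 weaker, 2 stronger). Replicate numbers were shared only as numbers, with correlations between groups of -0.00596 to 0.0363 at 90 min and -0.0893 to 0.0399 at 24 h. Depth of 26.2 M to 40.2 M gene reads at 90 min and 22.2 M to 24.6 M at 24 h limits genes with few reads, whose changes rest on counts in 1 group.

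With library size alone, falls at 90 min numbered 3696 in Smad4RE cells (1616 reported) and 1118 in the difference between responses (578 reported), and the Cdh1 difference was -0.016 instead of 0.03. With the DESeq2 Wald test 838 genes fell in Smad4RE cells, 135 fell in Vector cells, and the difference had 737 higher and 296 lower. For these the cause was not tested. Doxycycline under the inhibitor, fitted on only the compared groups, gave 1160 rises and 1011 falls (2054 and 1805 reported) from 4 instead of 8 libraries. With TMM on the deposited values, Id1 under TGFb with against without doxycycline was -0.0026 instead of 0.01, and the cause was not tested.

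With each library left out, counts in Vector cells ranged from 495 to 754 rises and 170 to 424 falls. The difference at 24 h ranged from 586 to 2667 higher and 689 to 2999 lower, and doxycycline under the inhibitor from 814 to 3281 rises and 748 to 2872 falls. The high ends at 24 h came without inhibitor alone replicate 2. Its pair differed most and all 24 h comparisons shared 1 spread, so leaving it out also changed that spread. Calls for doxycycline under TGFb, which compares no inhibitor library, were most numerous without it too. Klf5, Zeb1, Vim and Foxa1 kept the same log2 changes there, so the shared spread made that difference. Its part in comparisons whose log2 changes also moved was not tested. Uncalled genes that changed sign were Smad4 in Vector cells (-0.048 to 0.019), Id1 in the difference at 90 min (-0.21 to 0.050), Sox4 (-0.13 to 0.45) and Klf5 (-0.084 to 0.36) in the difference at 24 h, and Id1 under TGFb with against without doxycycline (-0.041 to 0.054). The cause was not tested.

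With an estimated correlation, lists past the threshold went from 7 to 2 in Smad4RE cells, 9 to 1 in Vector cells, 10 to 2 in their difference, 8 to 0 between the lines, 6 to 1 without doxycycline, 6 to 1 with it, 6 to 0 in the difference at 24 h, 7 to 1 for doxycycline under TGFb and 3 to 0 under the inhibitor. Early rises were no longer past it at 24 h without (0.40) or with doxycycline (0.35), nor early falls without it (-0.31). From fewer genes, early rises of a log2 of at least 1 passed camera with it (adjusted p = 0.0282 without and 0.0168 with doxycycline). Early falls of that size did too (0.0282 and 0.0161). The estimate gives larger correlations to lists whose genes vary together, which widens the error of the list mean. Among genes changed by a log2 of at least 1, the shares with a larger response were 68.7% of rises and 55.7% of falls at 90 min, and 27.0% and 26.9% at 24 h, from fewer genes. Early falls of that size had a median of 0.061 for doxycycline under TGFb, against -0.02 for all early falls. Camera called neither, fry called the first, and the cause was not tested.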

Other observations

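Tests chosen only after the result was seen were those of sequencing depth, less Sox4 protein and, for the receptor signal, both forms that used genes of the 24 h experiment.

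Besides Sox4, other genes read lower with doxycycline in both states at 24 h, and some answered TGFb in opposite ways. The Hippo pathway factor gene Tead2 read 1527 ± 103 normalized counts with inhibitor and 4494 ± 190.3 with TGFb, but 255 ± 28.8 and 243 ± 16.4 with doxycycline (SD, n = 2). Igsf9 read 925 ± 0.576 and 2284 ± 167 without doxycycline and 356 ± 6.86 and 152 ± 3.14 with it, so its rise with TGFb turned into a fall. Marcksl1 went from 696 ± 10.9 to 1717 ± 26.0 without doxycycline and stood at 76.9 ± 1.01 and 93.5 ± 7.18 with it. Fosb rose with TGFb from 350.2 ± 6.87 to 1058 ± 156 without doxycycline and fell from 791 ± 101 to 390 ± 23.8 with it. Elf3 did the reverse, from 342 ± 9.52 to 187 ± 14.0 without doxycycline and from 381 ± 18.9 to 664 ± 34.9 with it. Il11 stood at 5050 ± 69.1 with TGFb alone and 4033 ± 555 with doxycycline and TGFb.

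Genes on chromosome 15 were higher in Smad4RE than in Vector cells under the inhibitor. Their median lay 0.380 above that of the other chromosomes, and 84.8% of them (395 of 466) lay above that median, which argues against a few strongly changed genes. The medians of 5 stretches along the chromosome were 0.38, 0.29, 0.40, 0.34 and 0.39. The lowest, 0.291, passed the lower bound written before for an extra copy of the chromosome in the Smad4RE line. That bound set no expected size, and the usual number of copies in these lines is not known. The values therefore leave an extra copy possible but do not show one. Chromosomes 12 and 17 shifted the other way, each with a median of -0.14. A gain in one line and a loss in the other give the same ratio. DNA copy number was not examined, since the 6 chromatin libraries of the series were not analysed here. The biology of the design, restored Smad4, was not tested apart from this.

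The libraries with inhibitor alone differed more than other pairs, with 513 of 10733 genes (4.78%) more than 0.5 log2 apart, against 84, 81 and 123 in the others, and a replicate chi-square per degree of freedom of 24.2. The ratio of their read totals was 1.02, which argues against depth. Of the 235 genes this far apart and called for TGFb with doxycycline, 47.7% (interval 41.1 to 54.3) differed in the direction of that response, which argues against incomplete receptor block as the whole cause. Some loss of block in replicate 2 cannot be told apart from none, since genes up at least 2-fold with TGFb and doxycycline shifted by -0.00098 relative to those down, but early rises were 0.120 higher (interval 0.104 to 0.131, between the bounds written before), mesenchymal genes 0.218 and TGFb components 0.113, while direct Smad targets were 0.039 higher and early falls were not lower (0.026). Cell cycle genes shifted by 0.053 (interval -0.055 to 0.097), which argues against a large difference in the share of dividing cells. The intervals given here take genes as independent and would be wider where genes vary together. The cause of the difference between these libraries stays open.

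Doxycycline moved genes under the inhibitor, and its action on mitochondrial translation cannot be told apart from none, since stress response genes had a median of -0.069 with an interval of -0.264 to 0.186, 6 rising and 9 falling. An interferon response to the shRNA cannot be told apart from none either, since interferon genes had a median of 0.153 (interval 0.016 to 0.370, 7 rose and 0 fell) without passing as a list. Less Sox4 protein cannot be told apart from other actions, since values go both ways. Genes called under the inhibitor, a choice that favours a smaller effect elsewhere, changed no further under TGFb (median signed difference -0.0034, quartiles -0.243 to 0.278) and share the inhibitor libraries, but under TGFb 6336 genes were called against 3859, 1134 against 388 of them at least 2-fold. Of those called under the inhibitor 2659 were called in the same direction under TGFb and 137 in the opposite one, with no control shRNA to separate doxycycline from Sox4.

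Genes with the largest differences between the libraries with inhibitor alone included Bmpr2 (64.0 and 191 normalized counts), Ar (42.7 and 137), Cbl (182 and 490), Zbed6 (389 and 949) and Nrip1 (166 and 405). At 90 min Xirp2 stood at 0.0156 and 0.0253 CPM in Vector cells and 3.81 and 5.17 CPM in Smad4RE cells, with inhibitor and TGFb.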
